A study of Mus musculus with 24 samples.

How the data were processed

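RNA from brain hemispheres of mice was measured by polyA RNA-seq in 24 libraries, 6 from each of 4 genotypes. The groups were wild-type (WT), Tsc2+/-, Hexb-/-, and the double mutant that is Hexb-/- and Tsc2+/-. Group and replicate number were taken from the sample titles in the labels, and no sample was left without a group. Per the labels' protocols, each RNA came from a single hemisphere, total RNA was extracted with a column kit, and libraries were made with polyA selection. The labels do not state that the 6 libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Sex, age and strain background were not given in the sources used here.

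The values used were counts of reads per gene as the authors deposited them. Per the submitters' processing notes, reads were handled with fastp, aligned with HISAT2 2.0.5 to the mm10 (GRCm38) genome and counted with featureCounts 1.5.0-p3. Mapping settings, the strand setting of the counting and the annotation release were not given in the sources used here. Reads from a gene and an antisense or overlapping partner were therefore not separated here, and how the counting treated reads matching several places was likewise not given in the sources used here. The count table held 54532 genes, of which 36189 had at least 1 read. Library totals lay between 15335480 and 17048763 counts, so that 1 CPM (a count scaled to library size) stood for 15.3 to 17.0 counts. The authors also deposited tables of their own comparisons, with log2 fold changes and unadjusted and adjusted p-values, which per the submitters' processing notes were made with DESeq2 1.20.0. Those deposited p-value tables were checked and held only genes with an unadjusted p of at most 0.05. Their log2 fold changes were used solely to set beside the values computed here, and the table labelled as WT against Tsc2+/- was turned round so that higher means higher in Tsc2+/-. FPKM tables were not used.

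Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood method (glmQLFit and glmQLFTest) on the counts, with TMM normalization and filterByExpr by group, which kept 17537 genes; these held 99.9% of the counts in the library with the lowest share. TMM factors ranged from 0.985 to 1.02. All 24 libraries entered 1 fit with a mean per group and no covariate. The contrasts were Hexb-/- against WT, double mutant against Hexb-/-, Tsc2+/- against WT, double mutant against Tsc2+/-, double mutant against WT, and the interaction, which is the difference between the effects of Hexb loss with and without the loss of 1 Tsc2 allele. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Means and SDs are of CPM on TMM-scaled library sizes (n = 6), and log2 fold changes and their standard errors come from edgeR.

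Gene lists, 38 in number, and the tests, groups and alternatives were written down before the data were examined. The lists covered cell types (homeostatic and disease-associated microglia, infiltrating macrophages and monocytes, lymphocytes, red blood cells, reactive and homeostatic astrocytes, myelinating, precursor and newly formed oligodendrocytes, general, excitatory and inhibitory neurons, choroid plexus, ependymal, endothelial and pericyte, and meningeal fibroblast markers), regions (cerebellum, striatum, thalamus, and hypothalamus with pituitary), and processes (lysosome, v-ATPase, autophagy, mTOR pathway, ATF4 amino acid response, cholesterol synthesis, fatty acid synthesis, glycolysis, ribosomal proteins, mitochondrially encoded genes, complement, antigen presentation, interferon response, cytokines and chemokines, sphingolipids and gangliosides, immediate early genes, and sex-linked genes). Hexb and Tsc2 were in no list. Some genes stood in more than 1 list: 7 of the disease-associated microglia genes, 13 of the lysosome genes and 9 of the sphingolipid genes. So did 3 of the cytokine and chemokine genes, 1 interferon response gene and 1 myelinating oligodendrocyte gene. The glycolysis list tested 20 gene models for 19 symbols, because Aldoa names a pair of gene models. Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation, and p-values were adjusted over the lists of a comparison. The sex-linked list had a single tested member, Xist, and was not tested as a list. Xist stood at 599 to 814 CPM in the 24 libraries. Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads over the 24 libraries, so every library had the pattern of female tissue. List members were counted as having risen or fallen over all genes, and again adjusted over the list alone.

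A Hexb response score was the mean log2 CPM over genes changed by the main effect of Hexb (both Hexb-null groups against both others), computed separately for the genes higher (2584) and lower (2561). Double mutant and Hexb-/- scores were compared by a two-sided exact permutation test over all 924 arrangements of 12 libraries. The response with 1 Tsc2 allele lost was also given as a percent of the response without that loss, with a 95% interval from 10000 bootstrap draws of libraries. Calls within 10 Mb of Hexb or Tsc2 were compared with calls elsewhere by Fisher's exact test, with the targeted gene left out. The named genes followed a rule: Hexb and Tsc2 in each comparison, and in Hexb-/- against WT, double mutant against Hexb-/- and Tsc2+/- against WT up to 8 higher and 8 lower genes with the largest log2 fold changes among protein-coding genes with adjusted p under 0.05, a mean of at least 1 CPM over 12 libraries, an informative symbol and no overlap between the 2 groups' CPM ranges. Up to 4 members with the smallest p of each described list were added. In the remaining comparisons Hexb, Tsc2 and genes already named were followed.

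Sequence copies of genes near Tsc2 were searched with BLAST+ 2.17.0 in transcripts of the GRCm38 reference. Transcripts of genes off chromosome 17 were matched to transcripts of the 523 tested genes within 20 Mb of Tsc2, with at least 80% identity over at least 50% of the transcript, and 16685 of 16702 genes had a transcript to search. This search was added after the data were seen, and it was changed once, from the longest transcript of each gene near Tsc2 to all of its transcripts, after the first outcome was seen; both outcomes are given. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for that search and for the figures.

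The alternatives were DESeq2 size factors, no filter beyond 1 read, DESeq2 1.42.0 (Wald test), limma voom with quality weights, fits of only the 12 libraries compared, the replicate number as a block, Xist as a covariate, windows of 5 and 20 Mb, a stricter signature, and each library left out in turn. Named genes without WT replicate 2 and lists with each library left out were added after the data were seen, as were the sums of reads over a gene and its copies. Replicates were checked for duplicate deposits: the 60 pairs within groups had chi-square values per degree of freedom from 2.71 to 9.34, so no pair agreed within sampling noise. The edgeR test was tested on simulated data drawn for the 24 libraries, of which 17196 genes passed the filter. Changed genes were drawn only from those above 1 CPM in WT, so recovery of genes at lower levels was not examined. In Hexb-/- against WT the test recovered 31 of 50 genes changed 1.2-fold, 38 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 50 of 50 changed 3-fold, with 10 false calls. With no change simulated between Tsc2+/- and WT it made 0 calls. A simulated Hexb response of 50% was returned as 50.4%, and camera passed 2 of 100 random unchanged lists at an unadjusted p under 0.05. Genes were drawn independently of each other in these simulated data. The check therefore cannot tell whether the preset correlation of 0.01 is enough for lists whose members vary together.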

Results

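PolyA RNA was sequenced from brain hemispheres of mice of 4 genotypes, with 6 libraries per genotype. Hexb encodes the beta subunit of the lysosomal enzyme beta-hexosaminidase, and mice without it store gangliosides in neurons and model Sandhoff disease. Tsc2 encodes tuberin, which restrains the growth kinase complex mTORC1, and mice heterozygous for Tsc2 keep 1 working allele. The groups were wild-type (WT), Tsc2+/-, Hexb-/-, and the double mutant that combined both changes. The deposited counts gave library totals of 15335480 to 17048763, and 3.29% to 4.53% of the counts of a library lay in mitochondrially encoded genes. After a filter on low counts, 17537 genes were tested. The labels tie each RNA to 1 hemisphere and do not state separate animals, so the p-values measure the spread between these libraries.

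The targeted genes were examined first in every library. Hexb (ENSMUSG00000021665, chromosome 13, 97176331 to 97198357, GRCm38) stood at 59.8 ± 7.97 CPM (counts scaled to library size; mean ± SD, n = 6) in WT and 58.7 ± 4.28 in Tsc2+/-. In Hexb-/- it stood at 10.2 ± 1.25 CPM and in the double mutant at 11.4 ± 1.11 CPM. Each of the 12 Hexb-null libraries lay below each of the others for Hexb. Reads assigned to Hexb thus remained in the Hexb-null brains. The annotated span of Hexb overlaps that of Gfm2, whose mean was 33.3 CPM. Tsc2 (ENSMUSG00000002496, chromosome 17, 24595816 to 24632630) stood at 143 ± 8.05 CPM in WT and 154 ± 11.7 in Hexb-/-, against 92.8 ± 3.97 in Tsc2+/- and 95.3 ± 5.71 in the double mutant. The annotated span of Tsc2 overlaps that of Pkd1. By edgeR, Hexb fell by 2.54 on the log2 scale in Hexb-/- against WT (SE 0.0825, adjusted p = 2.69e-20). Tsc2 fell by 0.62 in Tsc2+/- against WT (SE 0.0475, adjusted p = 1.52e-10) and by 0.69 in the double mutant against Hexb-/- (SE 0.0473, adjusted p = 9.21e-12). Hexb did not pass the edgeR test between the double mutant and Hexb-/- (log2 fold change 0.16, adjusted p = 0.485), nor did Tsc2 between Hexb-/- and WT (0.10, adjusted p = 0.139). In the authors' deposited table the log2 fold change of Hexb was −2.55 in Hexb-/- against WT, and that of Tsc2 was −0.63 in Tsc2+/- against WT.

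**Figure D1:**
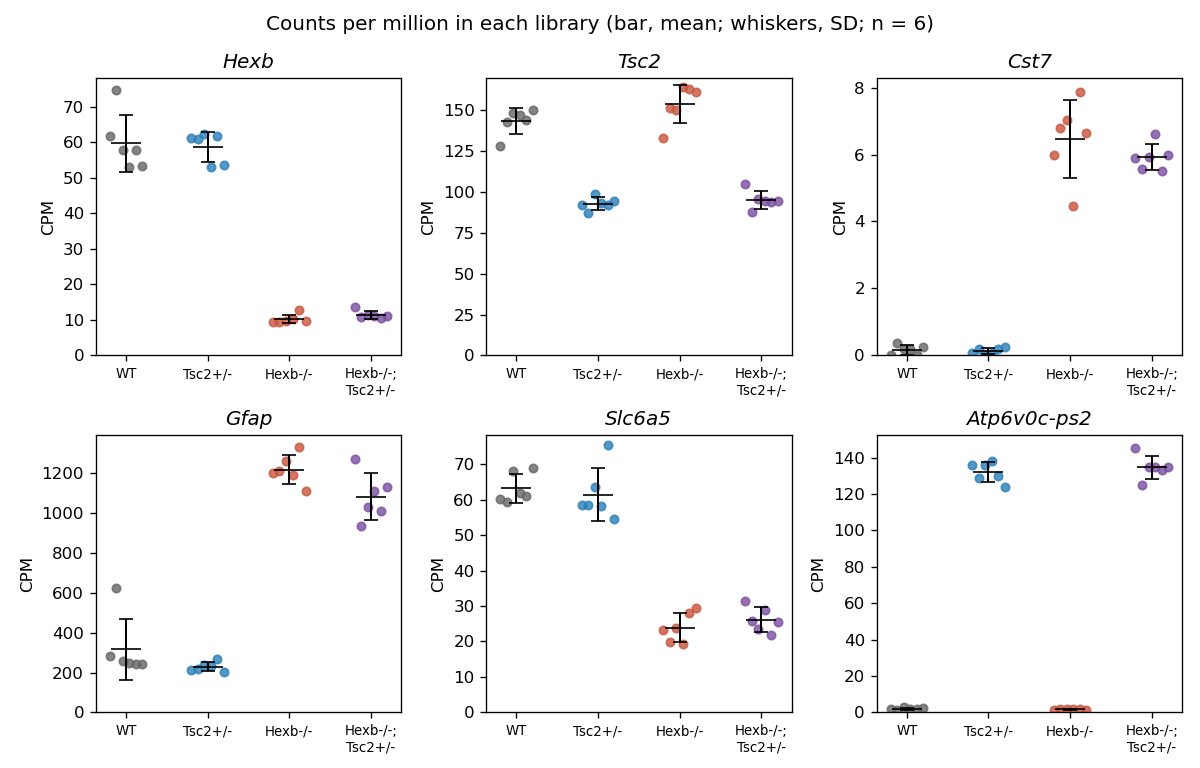
Library-scaled counts (CPM) of Hexb, Tsc2, Cst7, Gfap, Slc6a5 and Atp6v0c-ps2 in each of the 24 libraries (points), by genotype, with the mean (bar) and SD (whiskers, n = 6). Hexb and Slc6a5 were lower and Cst7 and Gfap higher in both Hexb-null groups, and Tsc2 was lower in both Tsc2+/- groups. Reads counted on Atp6v0c-ps2 stood at 1.95 and 1.66 CPM in WT and Hexb-/-, and at 132 and 135 CPM in Tsc2+/- and the double mutant. This pseudogene is near-identical to Atp6v0c, which lies near Tsc2, so its reads cannot be assigned with certainty.

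The first comparison asked how the brain transcriptome differed once Hexb was lost on a Tsc2 wild-type background. Among the genes that rose were markers of activated microglia and of astrocytes. Cst7, which encodes the cysteine protease inhibitor cystatin F, rose 37.0-fold, from 0.167 ± 0.145 CPM in WT to 6.47 ± 1.16 CPM in Hexb-/- (n = 6; edgeR log2 fold change 5.21, SE 0.284, adjusted p = 1.28e-14; chromosome 2, 150570415 to 150578944). Gpnmb, a glycoprotein of lysosome-rich phagocytes, rose 7.07-fold, from 3.16 ± 0.643 to 22.4 ± 4.14 CPM (edgeR adjusted p = 4.57e-16; chromosome 6, 49036546 to 49070929). Gfap, the intermediate filament of astrocytes, rose 3.84-fold, from 317 ± 152 to 1220 ± 73.5 CPM (edgeR adjusted p = 6.89e-11; chromosome 11, 102887336 to 102900912). In the other direction, Slc6a5, the neuronal glycine transporter, fell by 1.40 on the log2 scale, from 63.2 ± 4.16 to 23.9 ± 4.11 CPM (edgeR SE 0.0902, adjusted p = 6.59e-13; chromosome 7, 49910146 to 49963856). Glra1, a subunit of the glycine receptor, fell by 1.44 (edgeR SE 0.135, adjusted p = 3.24e-09; chromosome 11, 55514238 to 55608198).

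In all, edgeR called 2419 of 17537 genes changed between Hexb-/- and WT, 1193 higher and 1226 lower. Changes of at least 2-fold went mostly upward, with 140 genes higher and 19 lower in Hexb-/-. Besides Cst7 and Gpnmb, the largest rises under the selection rule were those of Itgax (log2 fold change 3.58, edgeR adjusted p = 8.55e-11), the sialic acid receptor Cd22 (3.26), the transglutaminase Tgm1 (3.11), Serpinf2 (2.87), Ly9 (2.80) and the acute-phase inhibitor Serpina3n (2.49, edgeR adjusted p = 5.37e-12). Without WT replicate 2 the log2 fold changes of Itgax, Tgm1 and Ly9 were 4.48, 4.38 and 3.69, so that library lowered these values. The order of Itgax, Tgm1 and Ly9 among themselves was the same, while their places among the other genes listed may shift. The largest falls after Glra1 and Slc6a5 were those of Lingo4 (−1.26), the transporter Abca8a (−0.83), Cmya5 (−0.69), Dapk2 (−0.69), the synaptic vesicle protein Sv2c (−0.69) and the opioid receptor Oprm1 (−0.66). Their edgeR adjusted p ran from 2.05e-13 for Sv2c to 0.0237 for Dapk2. The span of Oprm1 overlaps the more abundant Ipcef1, so part of its reads is uncertain. The authors' deposited table held 2215 genes with adjusted p under 0.05, and 2096 of them were also called here, each in the same direction.

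Microglial genes rose as a group. Of 26 disease-associated microglia genes, 23 rose over all genes and 23 rose adjusted over the list alone (camera adjusted p = 4.46e-42, and adjusted p = 0.000514 with an estimated correlation). Examples besides Cst7 were the phagocytic receptor Trem2 (12.4 ± 1.67 to 36.1 ± 2.60 CPM, log2 fold change 1.54), Cd68 (6.48 ± 1.45 to 22.1 ± 1.62 CPM, 1.77) and the protease Ctsd (209 ± 13.1 to 401 ± 22.0 CPM, 0.94), each n = 6. Homeostatic microglia genes were mixed. Of 14, 6 rose, among them Fcrls (0.94) and the fractalkine receptor Cx3cr1 (0.39), 1 fell, the fructose transporter Slc2a5 (−0.59), and 7 did not pass. Adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.00134, and adjusted p = 0.218 with an estimated correlation). Cx3cr1 spans other expressed genes, Wdr48 among them, and its counts are uncertain to that extent. Infiltrating macrophage and monocyte genes did not pass as a list (1 rose, 1 fell and 5 did not pass of 7; camera adjusted p = 0.758). Of lymphocyte genes only 2 were expressed enough to test, and their list did not pass (camera adjusted p = 0.812).

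Lysosomal and immune genes rose alongside. Among 47 lysosome genes, 33 rose, 1 fell and 13 did not pass. Adjusted over the list alone, 36 rose and 2 fell (camera adjusted p = 2.08e-29, and adjusted p = 0.000514 with an estimated correlation). The cathepsin Ctsl rose from 75.3 ± 3.68 to 118 ± 4.69 CPM and the tetraspanin Cd63 from 50.7 ± 4.99 to 89.1 ± 6.28 CPM (n = 6). Of the subunits of the v-ATPase, the proton pump of the lysosome, 6 of 16 rose and 10 did not pass. Within that list alone 7 rose (camera adjusted p = 0.00866, and adjusted p = 0.336 with an estimated correlation). Atp6v0b had a log2 fold change of 0.18 (edgeR adjusted p = 4.74e-05). Complement genes rose in 8 of 11 cases, 9 adjusted over the list alone (camera adjusted p = 1.95e-14, and adjusted p = 0.0338 with an estimated correlation). They included C1qa (36.3 ± 10.6 to 105 ± 4.16 CPM), C1qb (38.4 ± 10.5 to 94.3 ± 4.69 CPM) and C4b (41.1 ± 16.1 to 219 ± 20.4 CPM). Reads of C4b may be shared with its near-identical neighbour C4a. Interferon response genes rose in 17 of 20 cases, 18 adjusted over the list alone (camera adjusted p = 2.64e-17, and adjusted p = 0.0338 with an estimated correlation). Ifit3, which has close paralogs, had a log2 fold change of 1.23 (edgeR adjusted p = 1.82e-07), and Bst2 rose likewise (edgeR adjusted p = 4.95e-06). Of 11 cytokine and chemokine genes, 5 rose and 6 did not pass, 6 adjusted over the list alone (camera adjusted p = 4.81e-07, and adjusted p = 0.0541 with an estimated correlation). Among them Ccl4 (3.60), Ccl3 (2.55) and Cxcl10 (2.33) remained below 5 CPM in each group's mean. Their log2 fold changes were 5.39, 3.20 and 4.96 without WT replicate 2. The span of Cxcl10 overlaps that of Art3.

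Of 14 antigen presentation genes, 9 rose by edgeR, DESeq2 and voom alike, 2 class II genes were called lower by edgeR and 0 by DESeq2 and voom, and 3 did not pass by edgeR. Adjusted over the list alone 9 had risen and 5 fallen. Their median log2 fold change was 0.55 and their mean 0.12 (camera adjusted p = 1.73e-05, and adjusted p = 0.336 with an estimated correlation). The class I genes B2m (63.6 ± 10.2 to 126 ± 7.46 CPM) and H2-D1 (75.2 ± 17.9 to 137 ± 9.18 CPM) rose, the latter from a family of similar genes that may share reads. WT replicate 2 stood apart from the other WT libraries for these groups. The 2 class II genes called lower no longer passed without it (H2-Ab1 at 0.04 and H2-Aa at 0.02 on the log2 scale, edgeR adjusted p = 0.92 and 0.965). Its H2-Ab1 stood at 27.7 CPM, against 1.71 to 2.60 in the other WT libraries and 2.39 ± 0.338 in Hexb-/-, and its H2-Aa, chosen after its values were seen, at 26.1 CPM, against 1.77 to 3.33 and 2.35 ± 0.601 CPM. In the same library Gfap stood at 626 CPM against 242 to 285, and the antigen presentation score was 1.28 against −0.42 to −0.07. Its scores were also above those of the other WT libraries for disease-associated microglia (0.772), interferon response (1.06), complement (0.997), cytokines (1.56) and reactive astrocytes (1.28), each as the mean log2 CPM minus the WT mean. Without WT replicate 2, a setting added after the data were seen, 2545 genes were called, 2110 of them among the 2419, and the same 15 lists passed.

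Astrocyte genes rose, with 11 of 19 reactive astrocyte genes risen and 8 not passing, and 12 risen adjusted over the list alone (camera adjusted p = 2.48e-12, and adjusted p = 0.0799 with an estimated correlation). Besides Gfap, the asparaginase Aspg rose from 4.31 ± 1.49 to 13.3 ± 2.18 CPM and the filament gene Vim from 69.5 ± 15.4 to 116 ± 10.7 CPM (n = 6). Of 15 homeostatic astrocyte genes 6 rose, 1 fell and 8 did not pass, with 8 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000276, and adjusted p = 0.249 with an estimated correlation). Among them were the water channel Aqp4 (log2 fold change 0.68) and Sox9 (0.33).

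Some neuronal and myelin genes fell, by smaller amounts. Of 14 general neuron genes 6 fell and 8 did not pass, with 9 fallen adjusted over the list alone (camera adjusted p = 5.63e-06, and adjusted p = 0.0241 with an estimated correlation). The neurofilament genes led this group. Nefh fell by 0.47 on the log2 scale (238 ± 11.1 to 172 ± 3.76 CPM; edgeR adjusted p = 1.63e-10), Nefm by 0.39 and Nefl by 0.28. The annotated spans of Nefm and Nefl overlap. Thalamic markers fell in 5 of 7 cases, 6 adjusted over the list alone (camera adjusted p = 2.12e-06, and adjusted p = 0.0241 with an estimated correlation). They included Prkcd (−0.35), Ntng1 (−0.34) and Tnnt1 (−0.65). Markers of excitatory neurons (1 of 9 fell; camera adjusted p = 0.299), inhibitory neurons (0.747), striatum (0.812) and cerebellum (1 rose and 1 fell of 12; 0.599) did not pass as lists. By edgeR 0 of 12 inhibitory neuron markers and 0 of 10 striatal markers passed (1 lower and 1 higher unadjusted, and 0 by DESeq2 and voom). Of 25 myelinating oligodendrocyte genes 6 fell and 19 did not pass, with 9 fallen and 1 risen adjusted over the list alone (camera adjusted p = 0.00389, and adjusted p = 0.467 with an estimated correlation). Among them were Mal (−0.37) and Ugt8a (−0.34), the galactosyltransferase of myelin lipid synthesis.

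Ribosomal protein genes rose slightly, 23 of 79 over all genes and 43 adjusted over the list alone, with a median log2 fold change of 0.12 (camera adjusted p = 2.41e-11, and adjusted p = 0.336 with an estimated correlation). Fau (0.19) and Rpl14 (0.18) had the smallest p. Immediate early genes rose in 3 of 13 cases, 6 adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.467 with an estimated correlation), Npas4 among them (1.04, edgeR adjusted p = 0.0138). Their scores, as mean log2 CPM minus the WT mean, ran from −0.927 to 1.24 among the WT libraries. That range held the Hexb-/- mean of 0.839. The mTOR pathway list did not pass (8 rose, 2 fell and 30 did not pass of 40; 8 risen and 3 fallen adjusted over the list alone; camera adjusted p = 0.249). Even so, Flcn (68.2 ± 3.56 to 89.0 ± 5.22 CPM, edgeR adjusted p = 4.75e-07) and Rragd (132 ± 4.04 to 157 ± 9.75 CPM, edgeR adjusted p = 1.90e-05), which act in amino acid signalling at the lysosome, each rose. Sphingolipid and ganglioside genes were split, with 6 risen, 5 fallen and 21 not passing of 32 (7 and 6 adjusted over the list alone; camera adjusted p = 0.826). The alpha subunit partner of Hexb, Hexa, rose from 49.8 ± 7.55 to 70.3 ± 2.91 CPM and the glucocerebrosidase gene Gba by 0.31 on the log2 scale, while the ganglioside synthase gene St8sia1 fell by 0.24. Fatty acid synthesis genes did not pass as a list (1 rose and 5 fell of 14; camera adjusted p = 0.111, and 0.0322 without Hexb-/- replicate 5), with the desaturase Scd1 at −0.26. Cholesterol synthesis genes did not pass either (1 rose and 3 fell of 24; camera adjusted p = 0.577), with the rate-limiting Hmgcr at −0.20.

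The remaining lists did not pass in Hexb-/- against WT. Autophagy genes gave 3 risen and 21 not passing of 24 (camera adjusted p = 0.747), and precursor and newly formed oligodendrocyte markers 2 of 9 and 3 of 10 risen (camera adjusted p = 0.111 and 0.299). Of the ATF4 amino acid response genes 4 of 24 rose, 5 adjusted over the list alone, with a median of −0.03, a mean of 0.04 and a camera direction of higher (camera adjusted p = 0.678). Glycolysis genes gave 2 risen and 1 fallen of 20, with a median of −0.01, a mean of 0.02 and a camera direction of higher (camera adjusted p = 0.834). Endothelial and pericyte markers gave 2 fallen of 14, with a median of 0.01, a mean of −0.04 and a camera direction of lower (camera adjusted p = 0.577). Meningeal fibroblast markers gave 1 fallen of 9 and 0 adjusted over the list alone by edgeR, with a median of 0.05, a mean of −0.04 and a camera direction of higher (camera adjusted p = 0.758), and ependymal markers 1 risen of 6 (camera adjusted p = 0.645). By edgeR 0 members passed among hypothalamus and pituitary (6 tested, 1 lower unadjusted, 0 by DESeq2, 1 lower by voom; camera adjusted p = 0.249), choroid plexus (10; 0.812), red blood cell (5; 0.299) and mitochondrially encoded genes (13; 0.826). For these last 3 lists the unadjusted, DESeq2 and voom counts were each 0, and the mitochondrially encoded genes had a median of 0.01 and a mean of −0.09.

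**Figure D2:**
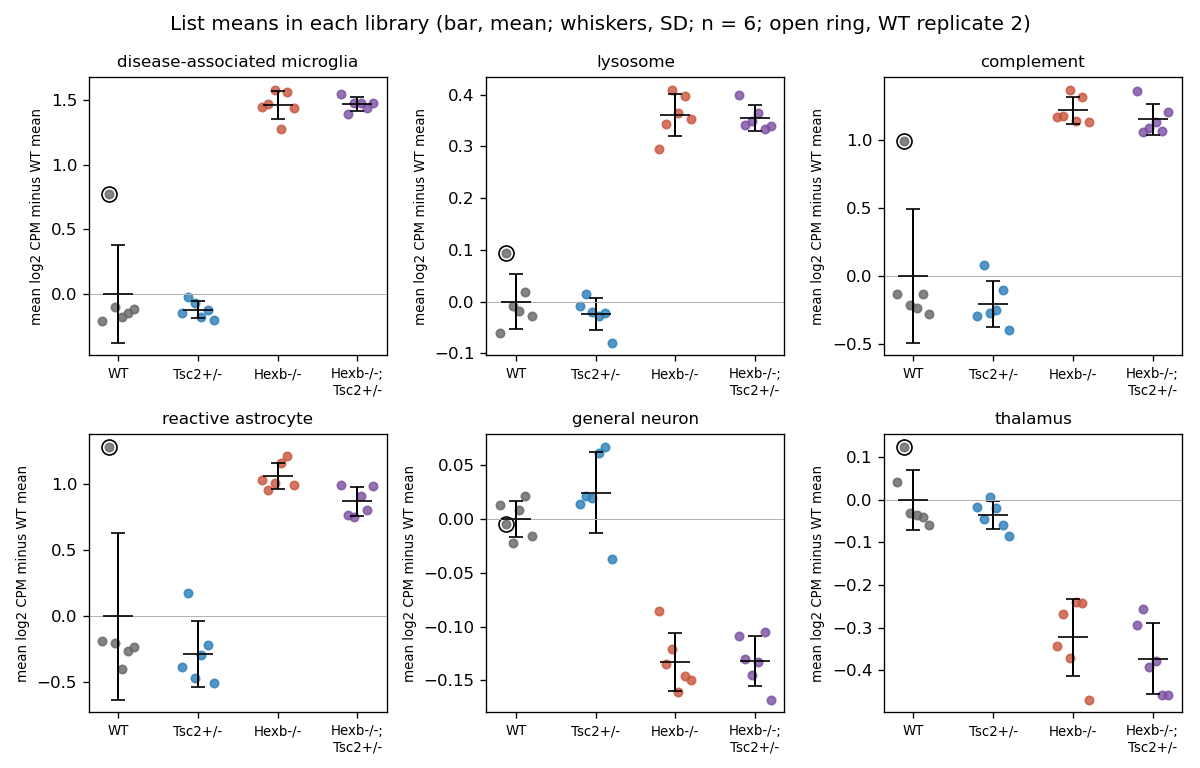
Mean log2 CPM of 6 gene lists in each library, minus the WT mean, by genotype (points), with the group mean (bar) and SD (whiskers, n = 6); the ring marks WT replicate 2. Both Hexb-null groups lay above WT and Tsc2+/- for disease-associated microglia and lysosome genes and below them for general neuron and thalamus genes, and WT replicate 2 lay at 0.772 for disease-associated microglia and 1.28 for reactive astrocytes.

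Genes near Hexb were called more often than genes elsewhere. Within 10 Mb of Hexb, 30 of 117 tested genes were called in Hexb-/- against WT (25.6%, against 13.7% elsewhere; odds ratio 2.17, Fisher's exact p = 0.000627). In the same window 40 of 117 were called in the double mutant against Tsc2+/- (odds ratio 2.22, Fisher's exact p = 0.000121). Sv2c and Cmya5 lie in this stretch of chromosome 13.

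The next question, posed by the series title, was whether the loss of 1 Tsc2 allele altered the transcriptome of the Hexb-null brain. By edgeR 52 of 17537 genes differed between the double mutant and Hexb-/-, among them genes on chromosome 17 and genes elsewhere that matched these in sequence. Atp6v0c, the membrane ring subunit of the v-ATPase, fell by 0.79 on the log2 scale, from 172 ± 7.29 CPM in Hexb-/- to 99.6 ± 2.84 CPM in the double mutant (n = 6; edgeR SE 0.0435, adjusted p = 3.58e-14; chromosome 17, 24163866 to 24169702). Its reads were also summed with those of its near-identical copy on chromosome 6, a step added after the data were seen. The sum was instead 0.429 higher in the double mutant (SE 0.0302, exact permutation p = 0.00216). How reads matching both places were counted was not given. The sum therefore cannot show whether total Atp6v0c RNA changed, and the direction of Atp6v0c is uncertain. The splicing factor gene Rnps1 fell by 0.59, from 108 ± 4.33 to 71.9 ± 3.14 CPM (edgeR SE 0.0399, adjusted p = 9.21e-12; chromosome 17, 24414675 to 24425895), and by 0.28 when summed with its copy (exact permutation p = 0.00216). The serine protease gene Prss41 rose 6.27-fold, from 0.361 ± 0.111 to 2.31 ± 0.156 CPM (edgeR SE 0.267, adjusted p = 9.24e-08; chromosome 17, 23836785 to 23844172), and Tagap 3.59-fold, from 1.59 ± 0.389 to 5.74 ± 0.855 CPM (edgeR SE 0.159, adjusted p = 3.24e-09; chromosome 17, 7926000 to 7934897).

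Of the 52 genes called between the double mutant and Hexb-/-, 30 were higher and 22 lower, and 11 of the 52 changed at least 2-fold. At an unadjusted p under 0.05, 2361 genes differed by edgeR, where 877 would arise with no effect. The 52 therefore need not be all that differ, although genes that vary together can also raise such a count. The other genes under the selection rule that rose were Hmga1b (log2 fold change 1.68), Dynlt1b (1.40), Fam183b (0.97), Slc22a3 (0.62), Cwf19l2 (0.38) and Hecw2 (0.22). Those that fell were Rfx2 (−0.66), Pkmyt1 (−0.57), Hmga1 (−0.50), Tagap1 (−0.47), Decr2 (−0.45) and Prdm15 (−0.32), with edgeR adjusted p from 6.64e-06 for Tagap1 to 0.0358 for Rfx2. Hmga1b and Hmga1, Tagap and Tagap1, and Dynlt1b and its tandem copies are near-identical or similar genes that may share reads. The span of Pkmyt1 overlaps the more abundant Paqr4, and the values of these genes are uncertain to that extent. Of 302 genes with an adjusted p under 0.05 in the authors' deposited table, 111 higher and 191 lower, 29 were also called here, each in the same direction. Depending on which single library was left out, the number of genes called ranged from 25 without Hexb-/- replicate 3 to 267 without Hexb-/- replicate 1. It was 32 and 29 without Hexb-/- replicates 4 and 5, and 133, 26, 28 and 31 without double mutant replicates 1, 2, 4 and 5. DESeq2 called 138 genes and limma voom 377.

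None of the lists of the Hexb response passed between the double mutant and Hexb-/-. By edgeR 0 of 26 disease-associated microglia genes passed (1 lower at an unadjusted p under 0.05, and 0 by DESeq2 and by voom; camera adjusted p = 0.947). Their median log2 fold change was −0.01 and their mean 0.01, and the camera direction was lower. Of 47 lysosome genes 0 passed (3 higher and 3 lower unadjusted; 0 by DESeq2, and 2 lower by voom; camera adjusted p = 0.985). Complement genes gave 0 of 11 (0 unadjusted, 0 by DESeq2 and voom; camera adjusted p = 0.774; median 0.01, mean −0.07). C4b stood at 219 ± 20.4 CPM in Hexb-/- and 193 ± 14.7 CPM in the double mutant (n = 6; edgeR log2 fold change −0.18, adjusted p = 0.557). Reactive astrocyte genes gave 0 of 19 (1 higher and 3 lower unadjusted, 0 by DESeq2 and voom; camera adjusted p = 0.231). In the fit without WT replicate 2 the reactive astrocyte list passed as lower (camera adjusted p = 0.0227). Immediate early genes (camera adjusted p = 0.0554) passed as lower without any 1 of WT replicate 2, Hexb-/- replicates 3 and 5 and double mutant replicates 2, 3 and 6 (camera adjusted p 0.0109 to 0.0475). Mitochondrially encoded genes, with the same adjusted p = 0.0554 by camera and a median of 0.12 (0 of 13 passing by edgeR, 0 unadjusted, 0 by DESeq2 and voom), passed as higher without Hexb-/- replicates 1 and 3 (0.0012 and 0.0253) and double mutant replicate 6 (0.0109). Choroid plexus genes (0.231) passed as lower without Hexb-/- replicate 4 and double mutant replicates 2 and 5 (camera adjusted p 0.0202 to 0.0494), and glycolysis genes (0.0554) without Hexb-/- replicate 5 and double mutant replicate 2 (camera adjusted p = 0.041 and 0.0304). Ribosomal protein genes (camera adjusted p = 0.635) passed as higher without Hexb-/- replicate 3 (0.0396). General neuron (camera adjusted p = 0.988), thalamus (0.635), myelin (0.821), interferon (0.579), antigen presentation (0.985) and cytokine (0.988) lists did not pass either. The mTOR pathway list did not pass with 0 of 40 members by edgeR (3 higher and 4 lower unadjusted, 0 by DESeq2, 1 higher by voom; camera adjusted p = 0.635). Nor did autophagy (0 of 24 by edgeR, 1 higher and 3 lower unadjusted, 0 by DESeq2, 1 lower by voom; camera 0.635) or ribosomal proteins (0 of 79 by edgeR, 6 higher and 4 lower unadjusted, 1 lower by DESeq2 and 1 by voom; 0.635, and 0.0396 as higher without Hexb-/- replicate 3). In the v-ATPase list 1 of 16 fell, Atp6v0c, whose direction is uncertain because of its copy (camera adjusted p = 0.728). A score that misses the threshold does not show that the groups were alike.

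Among the 37 lists tested, 2 passed with the preset correlation and neither with an estimated correlation. That number was 4 without WT replicate 2, 1, 5 and 4 without Hexb-/- replicates 2, 3 and 5, and 0, 5 and 4 without double mutant replicates 1, 2 and 6. Hypothalamus and pituitary markers were higher as a list, with a median log2 fold change of 0.46. Even so, 0 of 6 passed over all genes by edgeR (3 unadjusted, 0 by DESeq2, 2 by voom) and 3 rose adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.999 with an estimated correlation). Their scores were −1.43 and −0.669 in Hexb-/- replicates 2 and 4, against −0.444 to 0.2 in the other Hexb-/- libraries, and the list no longer passed without Hexb-/- replicate 2 (median 0.36, camera adjusted p = 0.0845) or without double mutant replicate 1 (median 0.50, camera adjusted p = 0.0685). Avp stood at 11.2 ± 4.74 CPM in Hexb-/- and 16.3 ± 1.99 CPM in the double mutant, and Pmch at 3.75 ± 1.09 and 5.43 ± 0.831 CPM (n = 6; edgeR adjusted p = 0.177 and 0.155). Endothelial and pericyte markers were lower as a list, with a median of −0.10. Of single members, 0 of 14 passed over all genes by edgeR (4 unadjusted, 2 by DESeq2, 3 by voom) and 3 fell adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.999 with an estimated correlation). The list no longer passed without double mutant replicate 1, at the same median of −0.10 (camera adjusted p = 0.0655). Its members included the vascular growth factor receptor genes Kdr (−0.37, edgeR adjusted p = 0.106) and Flt1 (−0.24, edgeR adjusted p = 0.119) and the cadherin Cdh5 (−0.28, edgeR adjusted p = 0.074).

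Whether the response to Hexb loss was smaller with 1 Tsc2 allele lost was also asked of all responding genes together. Over the 2584 genes higher with Hexb loss, mean log2 CPM was 4.14 ± 0.04 in Hexb-/- and 4.11 ± 0.03 in the double mutant (n = 6), a difference of −0.03 (two-sided exact permutation p = 0.113). Over the 2561 genes lower with Hexb loss the means were 5.90 ± 0.02 and 5.91 ± 0.01, a difference of 0.02 (exact permutation p = 0.0931). Over the 13 of them that changed at least 2-fold the score was 0.28 higher in the double mutant (exact permutation p = 0.0152), and over the 169 higher genes of that size it was 0.07 lower (exact permutation p = 0.195). Relative to its own Tsc2-matched control, the response with 1 Tsc2 allele lost was 112% of that without this loss for the higher genes (95% bootstrap interval 96.5 to 136%) and 113% for the lower genes (interval 101 to 129%). Without WT replicate 2 these ratios were 104% and 111%. The ratios also depend on the controls, whose scores were compared after the result was seen. Tsc2+/- minus WT was −0.07 for the higher genes and 0.04 for the lower genes. Between the Hexb-null groups the differences of −0.03 and 0.02, which did not pass, ran toward a smaller response in the double mutant. The ratios thus reflect the shifted controls and do not show scores further from WT in the double mutant. The higher-gene difference between the double mutant and Hexb-/- passed without Hexb-/- replicate 1 (−0.05, exact permutation p = 0.0238). The lower-gene difference between these groups passed without Hexb-/- replicate 1 or replicate 6 (0.03 and exact permutation p = 0.013 in each case).

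The third comparison asked what the loss of 1 Tsc2 allele did in brains with intact Hexb. Several of the genes on chromosome 17 named above changed here too. Prss41 rose 10.5-fold, from 0.188 ± 0.138 CPM in WT to 2.05 ± 0.752 CPM in Tsc2+/- (n = 6; edgeR log2 fold change 3.39, SE 0.308, adjusted p = 9.27e-09), and Tagap rose 4.68-fold (edgeR SE 0.172, adjusted p = 1.76e-10). Atp6v0c fell by 0.77 on the log2 scale, from 167 ± 12.7 to 97.7 ± 5.67 CPM (edgeR SE 0.0436, adjusted p = 7.67e-14). Summed with its copy it was 0.447 higher (SE 0.0529, exact permutation p = 0.00216), a sum with the same limit as above. Rnps1 fell by 0.57, and by 0.27 when summed with its copy, and Tagap1 by 0.58. Immediate early and ribosomal protein genes were lower as lists, by camera with its preset correlation and not with an estimated correlation.

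By edgeR 119 genes were changed in Tsc2+/- against WT, 81 higher and 38 lower, 10 of the 119 at least 2-fold. At an unadjusted p under 0.05, 2650 genes differed by edgeR (1997 without WT replicate 2), where 877 would arise with no effect. Under the selection rule the further genes that rose were Hmga1b (1.53), Slc22a3 (0.58), Krt12 (0.56), Zfp983 (0.38), Lnpk (0.33) and the potassium channel gene Kcnb2 (0.32), with edgeR adjusted p from 1.77e-07 for Hmga1b to 0.0479 for Krt12. The span of Krt12 overlaps a more abundant antisense gene. Those that fell included the cytokine receptor-like gene Crlf1 (−0.56), Spsb3 (−0.47), the scavenger receptor Stab1 (−0.37) and Mknk2 (−0.29), a kinase of the translation factor eIF4E. Their edgeR adjusted p ran from 0.0202 for Mknk2 to 0.0298 for Crlf1 and Spsb3. Ddit4, an inhibitor of mTORC1 signalling, stood at 52.1 ± 10.4 CPM in WT and 38.3 ± 4.54 CPM in Tsc2+/- (n = 6; edgeR log2 fold change −0.44, adjusted p = 0.032). Ddit4 was the member of the ATF4 amino acid response list that fell (1 of 24; camera adjusted p = 0.785). This count moved with single libraries. Without WT replicate 2, 27 genes were called, all of them among the 119. Slc22a3, Krt12, Lnpk, Crlf1, Spsb3, Stab1, Mknk2, Rps2, Rpl18a and Ddit4 then no longer passed (edgeR adjusted p from 0.0602 for Crlf1 to 0.134 for Krt12). For Slc22a3, Crlf1 and Spsb3 that library lay within the range of the other WT libraries, so their lost calls do not show that it made the difference. For Krt12, Lnpk, Stab1, Mknk2 and Rps2 it lay outside that range. The count was 37 and 192 without WT replicates 3 and 6, and 51, 60, 29 and 75 without Tsc2+/- replicates 2, 4, 5 and 6, 20 with Xist as covariate and 292 by DESeq2. Every library expressed Xist (599 to 814 CPM) with 0 reads on the Y-linked genes, so the Xist covariate does not stand for a mix of sexes. The authors' deposited table held 346 genes with adjusted p under 0.05, and 93 of them were also called here in the same direction.

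Of 79 ribosomal protein genes 2 fell and 77 did not pass, with 10 fallen adjusted over the list alone and a median log2 fold change of −0.07 (camera adjusted p = 3.80e-08, and adjusted p = 0.917 with an estimated correlation). Those 2 were Rpl18a (156 ± 7.26 to 135 ± 5.58 CPM, edgeR adjusted p = 0.0234) and Rps2 (194 ± 8.82 to 171 ± 3.86 CPM, edgeR adjusted p = 0.0185), the latter with near-identical pseudogenes. Immediate early genes had a median of −0.65, with 0 of 13 passing over all genes by edgeR (12 lower unadjusted, 0 by DESeq2 and voom) and 10 fallen adjusted over the list alone (camera adjusted p = 9.81e-05, and adjusted p = 0.917 with an estimated correlation). Fosb stood at 14.1 ± 9.10 CPM in WT and 6.75 ± 0.639 in Tsc2+/-, and Arc at 146 ± 106 and 66.3 ± 42.1 (n = 6; edgeR adjusted p = 0.102 and 0.120). The ribosomal protein and immediate early lists also passed without WT replicate 2 (camera adjusted p = 1.16e-07 and 0.00351). Among the WT libraries the immediate early scores, as mean log2 CPM minus the WT mean, ran from −0.927 to 1.24.

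The remaining 6 lists that passed in Tsc2+/- against WT did so only with WT replicate 2 included, and not with an estimated correlation (adjusted p = 0.917 with an estimated correlation for each). The median without WT replicate 2 stayed about as large for homeostatic astrocyte genes (−0.05 in both fits) and mitochondrially encoded genes (0.16 and 0.14). It shrank for reactive astrocyte (−0.39 to −0.09), antigen presentation (−0.40 to −0.08) and cerebellar genes (−0.14 to −0.08), and turned for interferon response genes (−0.27 to 0.02). Reactive astrocyte genes had a median of −0.39 with 0 of 19 passing by edgeR (10 lower unadjusted, 0 by DESeq2 and voom; camera adjusted p = 0.00158, and 0.382 without WT replicate 2). Gfap stood at 317 ± 152 CPM in WT against 229 ± 23.6 in Tsc2+/-, with Vim at 69.5 ± 15.4 against 57.5 ± 6.51 (n = 6; edgeR adjusted p = 0.129 and 0.161). Antigen presentation genes had a median of −0.40, with 1 of 14 fallen, H2-T23 (log2 fold change −0.59, edgeR adjusted p = 0.0471), and 5 adjusted over the list alone (camera adjusted p = 0.0016, and 0.208 without WT replicate 2). Interferon response genes had a median of −0.27 and 0 of 20 passing by edgeR (4 lower unadjusted, 0 by DESeq2 and voom; camera adjusted p = 0.047, and 0.946 without WT replicate 2). This list was also lost without WT replicate 5 (0.0759) and without Tsc2+/- replicates 1, 4, 5 or 6 (camera adjusted p = 0.0682, 0.209, 0.0855 and 0.116), with medians that stayed between −0.27 and −0.22. Its member Oas1a stood at 1.11 ± 0.75 CPM in WT and 0.531 ± 0.116 in Tsc2+/-. Of homeostatic astrocyte genes, with Aldoc at −0.15, 0 of 15 passed by edgeR (7 lower unadjusted, 1 by DESeq2, 0 by voom) and 4 fell adjusted over the list alone (camera adjusted p = 0.0106, and 0.065 without WT replicate 2). Of cerebellar markers, with Grm4 at −0.24, 0 of 12 passed by edgeR (2 lower unadjusted, 0 by DESeq2 and voom; camera adjusted p = 0.0081, and 0.0921 without WT replicate 2). Tsc2+/- replicates 4 and 5 had cerebellar scores of −0.36 and −0.623, against −0.0743 to 0.0673 in the other Tsc2+/- libraries, and the list was also lost without either (camera adjusted p = 0.0945 and 0.343). Mitochondrially encoded genes were higher as a list, with 0 of 13 passing by edgeR (6 higher and 1 lower unadjusted, 0 by DESeq2, 1 by voom) and 4 risen adjusted over the list alone (camera adjusted p = 0.0118, and 0.0867 without WT replicate 2). Tsc2+/- replicate 2 scored 0.423 for them, against −0.00341 to 0.0908 in the other Tsc2+/- libraries, and without it the list was lost too (camera adjusted p = 0.0575). mt-Nd6, which overlaps mt-Nd5, stood at 899 ± 145 CPM in WT and 1130 ± 114 in Tsc2+/-. Disease-associated microglia (camera adjusted p = 0.18), lysosome (1 of 47 fell; 0.543), complement (0.0803, and 0.0225, 0.0138, 0.021 and 0.00975 as lower without WT replicates 3, 4 and 6 and Tsc2+/- replicate 2), mTOR pathway (0 of 40 by edgeR, 6 higher and 8 lower unadjusted, 1 lower by DESeq2 and by voom; 0.543) and autophagy lists (0.836) did not pass.

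Changes with the loss of 1 Tsc2 allele ran together in both Hexb backgrounds, in comparisons that share no library. Between Tsc2+/- against WT and the double mutant against Hexb-/-, 18 genes were called higher in both (0.139 for independent calls) and 8 lower in both (0.0477), 0 in opposite directions by edgeR, and 12 of these 26 lay off chromosome 17. Across the 17537 genes, which are not independent replicates, log2 fold changes correlated with r = 0.316 and Spearman rho = 0.307. Within 10 Mb of Tsc2, 15 of 342 tested genes were called in Tsc2+/- against WT (4.39%, against 0.599% elsewhere; odds ratio 7.61, 95% interval 4.06 to 13.3, Fisher's exact p = 9.74e-09) and 10 of 342 in the double mutant against Hexb-/- (2.92%, against 0.238%; odds ratio 12.6, interval 5.58 to 25.8, Fisher's exact p = 4.39e-08). Chromosome 17 held 22.0% and 31.4% of the calls, with Tsc2 left out.

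Several genes elsewhere in the genome that rose in both Tsc2 comparisons matched genes near Tsc2 in sequence; they were chosen after their values were seen. The processed pseudogene Atp6v0c-ps2 (chromosome 6, 37806086 to 37806550) stood at 1.95 ± 0.52 CPM in WT and 1.66 ± 0.23 in Hexb-/-, against 132 ± 5.29 in Tsc2+/- and 135 ± 6.45 in the double mutant (n = 6; edgeR log2 fold changes 6.08 and 6.34, adjusted p = 1.12e-32 and 6.17e-33). Its sequence matched Atp6v0c at 99.8% identity. Gm9825, on chromosome 6, rose from 0.472 ± 0.0968 CPM in WT to 16.9 ± 1.46 in Tsc2+/- and matched Rnps1 at 99.4%. Hmga1b, on chromosome 11, rose from 5.59 ± 0.803 to 16.1 ± 4.58 and matched Hmga1 at 99.8%. Tsc2+/- replicate 1 held Hmga1b at 7.01 CPM against 16.1 to 18.9 in the other Tsc2+/- libraries. The same library held Hmga1 at 67.7 CPM (others 42.7 to 49.5) and Decr2 at 31.9 (others 23.2 to 25.5), within the WT ranges, while its Tsc2 (91.7) and Atp6v0c (98.3) lay within those of the other Tsc2+/- libraries. Reads of such pairs cannot be assigned with certainty, so the levels of Atp6v0c, Rnps1, Hmga1, Rps2 and their copies are uncertain. Sums over gene and copy are uncertain too, because how reads matching several places were counted was not given. Summed over gene and copy, Hmga1 was at −0.12 in Tsc2+/- against WT (exact permutation p = 0.0758) and at −0.13 in the double mutant against Hexb-/- (exact permutation p = 0.0195), and Rps2 summed with 3 copies was at −0.11 and −0.09 (exact permutation p = 0.00433 and 0.11).

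**Figure D3:**
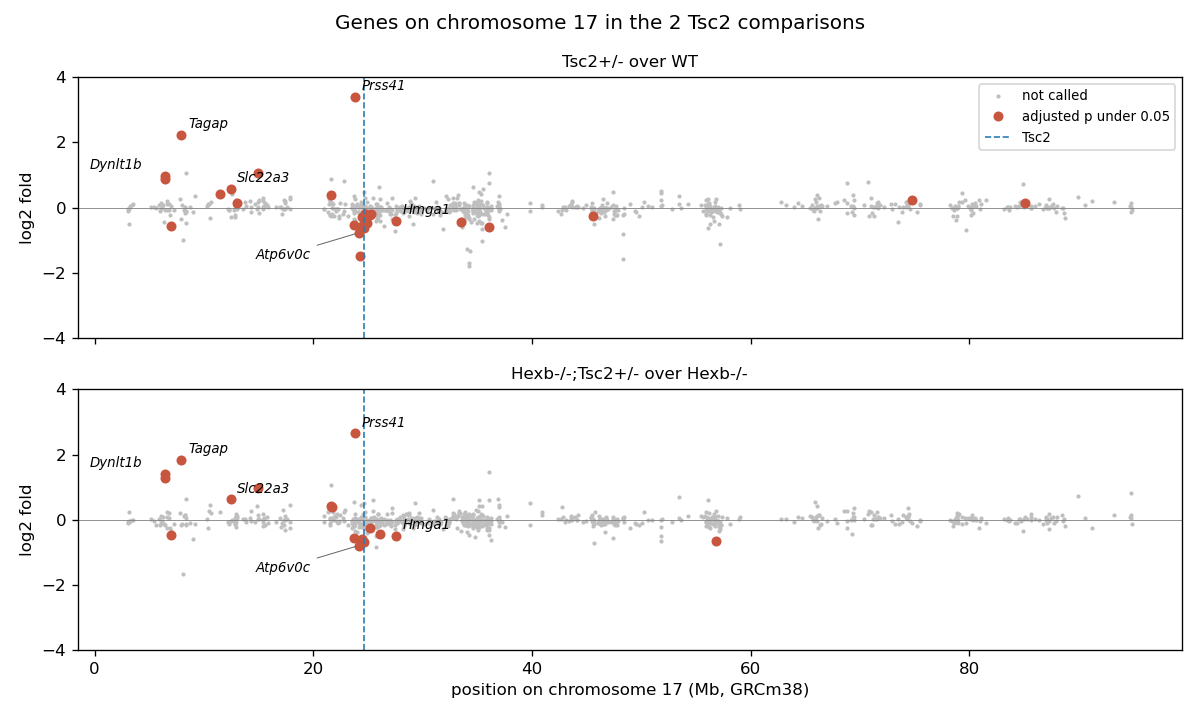
Log2 fold change of each tested gene on chromosome 17 against its position (Mb, GRCm38), in Tsc2+/- over WT (top) and in the double mutant over Hexb-/- (bottom); filled points had an edgeR adjusted p under 0.05, and the dashed line marks Tsc2. Called genes gathered near Tsc2 in both comparisons, with 15 and 10 of 342 genes within 10 Mb.

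The response to Hexb loss was then measured on the Tsc2+/- background, in libraries independent of the first comparison. The double mutant against Tsc2+/- showed the same leading genes. Cst7 rose 44.6-fold (edgeR log2 fold change 5.48, SE 0.301, adjusted p = 1.23e-14), Gpnmb 7.12-fold and Serpina3n 6.75-fold, and Itgax rose by 4.59 on the log2 scale. Slc6a5 fell by 1.23 on the log2 scale (61.4 ± 7.41 to 26.1 ± 3.48 CPM, n = 6; edgeR adjusted p = 7.85e-12), Glra1 by 1.42 and Sv2c by 0.73. Hexb itself fell by 2.36 (edgeR adjusted p = 1.49e-19) and Tsc2 did not pass (0.04, edgeR adjusted p = 0.649). By edgeR 3340 genes were changed, 1616 higher and 1724 lower, with 214 higher and 14 lower by at least 2-fold. Together with Hexb-/- against WT, 829 genes were called higher in both (110 for independent calls), 915 lower in both (121) and 0 by edgeR in opposite directions. Across the 17537 genes, which are not independent replicates, log2 fold changes correlated with r = 0.667 (rho = 0.578).

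Of the lists, 16 passed in the double mutant against Tsc2+/-, and 7 of them with an estimated correlation. Disease-associated microglia genes rose in 25 of 26 cases (camera adjusted p = 1.41e-36, and adjusted p = 0.00115 with an estimated correlation) and interferon response genes in 20 of 20 (1.55e-20, and adjusted p = 0.0202 with an estimated correlation). Lysosome genes rose in 36 of 47 cases and fell in 3 (9.44e-26, and adjusted p = 0.00115 with an estimated correlation). Ribosomal protein genes rose in 62 of 79 cases, 66 adjusted over the list alone (1.86e-23, and adjusted p = 0.0737 with an estimated correlation), and immediate early genes in 12 of 13 (2.92e-06, and adjusted p = 0.302 with an estimated correlation). General neuron genes fell in 8 of 14 cases (6.49e-07, and adjusted p = 0.0162 with an estimated correlation), thalamic markers in 6 of 7 (2.92e-06, and adjusted p = 0.0202 with an estimated correlation) and myelin genes in 11 of 25, with 1 risen (8.35e-05, and adjusted p = 0.302 with an estimated correlation).

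The size of the Hexb effect was compared between the Tsc2 backgrounds gene by gene with the interaction term. edgeR called 0 of 17537 genes (749 at an unadjusted p under 0.05, where 877 would arise with no effect), DESeq2 called 1 and voom 0. The smallest edgeR adjusted p was 0.0962, for Plekhf1, which was chosen after its value was seen. Thus the larger count on the Tsc2+/- background, 3340 against 2419, was not matched by single genes whose response was shown to differ. As lists, ribosomal protein genes had a larger response on the Tsc2+/- background (median log2 difference 0.08; camera adjusted p = 5.90e-11, and adjusted p = 0.821 with an estimated correlation), with 0 of 79 members passing alone by edgeR.

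**Figure D4:**
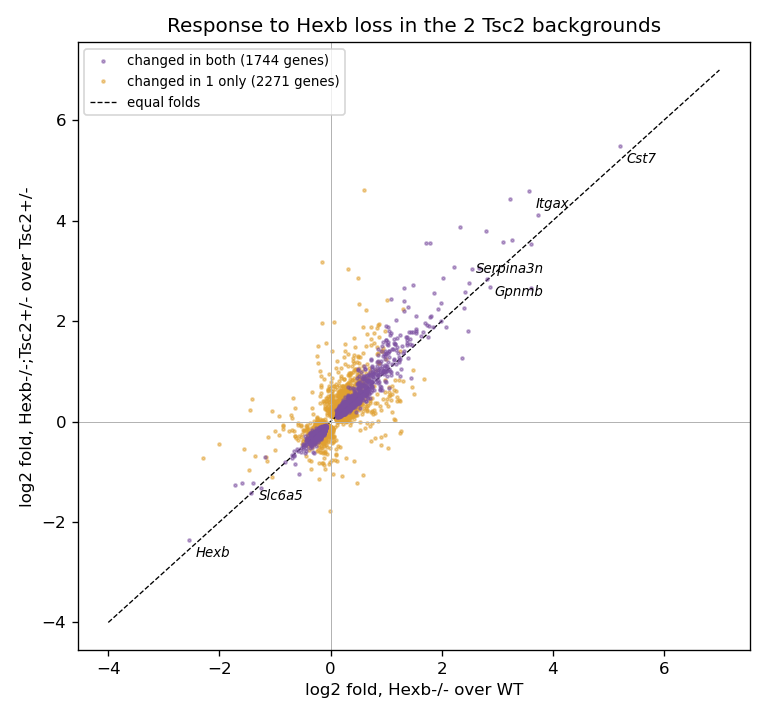
Log2 fold change with Hexb loss on the Tsc2 wild-type background (Hexb-/- over WT, x axis) and on the Tsc2+/- background (double mutant over Tsc2+/-, y axis) for genes called in both (1744) or in 1 of the comparisons; the dashed line marks equal folds. The 1744 genes called in both had the same sign in each, 829 higher and 915 lower.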

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

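In this part the tests of sequence copies, of the stretches of chromosomes 17 and 13 and of WT replicate 2 were chosen after the results were seen, as were the list values with a library left out.

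Single libraries far from the other 5 of their group were sought among 363 groups of values (genes, list scores and response scores), where chance gives about 1 in 20 (5 percent), or 18.2, and 42 were found, 21 of them in WT replicate 2. WT replicate 2 stood above the other WT libraries in CPM for Itgax (1.98, others 0.0663 to 0.432), Tgm1 (1.49, others up to 0.331), Ly9 (1.49, others 0.0633 to 0.365), Serpina3n (54.2, others 16.3 to 20.4), Cd68 (9.29, others 5.48 to 6.71), C4b (72.4, others 29.4 to 42.4) and Gfap (626, others 242 to 285). It did so too for Ccl4 (0.31, others up to 0.0663), Cxcl10 (5.01, others up to 0.309), Aqp4 (260, others 179 to 204), Stab1 (25.1, others 18.3 to 20.8), H2-Ab1 (27.7, others 1.71 to 2.6) and Oas1a (2.54, others 0.569 to 1.19). Its list scores stood apart for disease-associated microglia (0.772), interferon response (1.06), complement (0.997), reactive astrocytes (1.28), cytokines (1.56), antigen presentation (1.28) and cerebellum (0.224), and its score of genes higher with Hexb loss was 0.14 (others −0.0511 to 0.0153).

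Other libraries stood apart for single genes. In WT, replicate 1 held Tsc2 at 128 CPM (others 143 to 150), Nefh at 260 (227 to 238), Nefl at 414 (339 to 359) and mt-Nd6 at 1180 (805 to 928), and replicate 6 held Ctsl at 68.3 (74.9 to 78.4). In Hexb-/-, Hexb stood at 12.7 CPM in replicate 5 (9.44 to 10.3) and Fcrls at 40.3 (38.5 to 39.1), Sv2c at 91.1 in replicate 6 (80.9 to 83.8) and B2m at 111 (126 to 132). Also in Hexb-/-, Cx3cr1 stood at 45.4 in replicate 4 (52.4 to 56.6), Decr2 at 26.7 in replicate 3 (31.3 to 33.7) and Bnip3 at 64.6 in replicate 1 (49.4 to 54.7). In the double mutant, Hexb stood at 13.6 in replicate 1 (10.6 to 11.3) and Fam183b at 2.62 in replicate 6 (1.53 to 1.83). In Tsc2+/-, Hmga1b stood at 7.01 in replicate 1 (16.1 to 18.9) and H2-Ab1 at 3.26 in replicate 2 (1.31 to 1.81). Among list scores, Tsc2+/- replicate 2 stood apart for homeostatic astrocytes (−0.0165, others −0.0896 to −0.0648), endothelial and pericyte markers (0.105, others −0.141 to −0.0652) and mitochondrially encoded genes (0.423, others −0.00341 to 0.0908). WT replicate 3 did so for hypothalamus and pituitary markers (0.305, others −0.115 to 0.0103), and double mutant replicate 6 for mitochondrially encoded genes (−0.135, others 0.0713 to 0.166).

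The effect of Hexb loss differed between the Tsc2 backgrounds for 5 lists, by camera on the interaction. Median log2 differences were 0.0763 for ribosomal protein genes (adjusted p = 5.9e-11), 0.344 for interferon response (0.00232), 0.347 for antigen presentation (0.00789), −0.384 for choroid plexus (0.0115) and 0.296 for hypothalamus and pituitary markers (0.0174). With an estimated correlation each had an adjusted p = 0.821 by camera. Without WT replicate 2 ribosomal protein genes passed (camera adjusted p = 1.25e-09) and the other 4 did not (0.374, 0.39, 0.267 and 0.267, in the same order). The medians of these 4 were then 0.101, 0.111, −0.266 and 0.254. Interferon response and antigen presentation thus shrank most, and hypothalamus and pituitary markers least. With each of the 24 libraries left out in turn, ribosomal protein genes passed in 24 of 24 fits, interferon response in 23, antigen presentation in 22 (also lost without double mutant replicate 3, 0.0804), choroid plexus in 18 and hypothalamus and pituitary markers in 6. Choroid plexus was also lost without Hexb-/- replicates 3 and 5 (camera adjusted p = 0.118 and 0.0504) and double mutant replicates 1, 3 and 4 (0.111, 0.0679 and 0.0783). By edgeR 0 members of these lists passed alone.

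The first pattern weighed was that genes near Tsc2, and sequence copies of them, were called more often than others in Tsc2+/- brains, although chromosome 17 held 22% and 31.4% of the calls. Reads of genes near Tsc2 counted on copies elsewhere are a candidate explanation: of 11 genes higher in both Tsc2 comparisons off chromosome 17, 63.6% matched a gene within 20 Mb of Tsc2, against 0.363% of other genes (Fisher's exact p = 4.47e-15), 45.5% in the first form of the search (Fisher's exact p = 2.13e-10), and 11.4% of the 79 higher in either comparison (Fisher's exact p = 2.92e-11). Calls within 10 Mb of Tsc2 had odds ratios of 7.61 and 12.6, consistent with a linked stretch of chromosome 17, such as one from another strain, that differs between carriers and non-carriers, and in Tsc2+/- replicate 1 Hmga1 (67.7 CPM), Decr2 (31.9) and Hmga1b (7.01) lay near WT levels while Tsc2 (91.7) and Atp6v0c (98.3) did not, as a shorter stretch in that library could give. Among non-carriers, WT replicate 2 held Tmem181b-ps on chromosome 17 at 141 CPM (other WT 60.8 to 78.4, Tsc2+/- 120 to 165). It held Dynlt1b at 4.58 CPM (other WT 2.15 to 2.78, Tsc2+/- 3.63 to 6.34). Its Tagap (1.67) and Prss41 (0.124) stayed below all Tsc2+/- libraries. Tmem181b-ps and Dynlt1b thus did not follow the Tsc2 genotype in every library. Gapdh, picked after its values were seen, stood at 111 and 162 CPM in WT replicates 2 and 6 (others 10.7 to 13.2). It stood at 155, 142 and 48.5 CPM in Tsc2+/- replicates 1, 3 and 5 (others 11 to 13.3). In double mutant replicates 2 and 3 it was at 55.9 and 157 CPM (others 12.3 to 17.6), and in Hexb-/- at 11.8 to 17.6. Libraries within a group thus differed too, and the cause was not tested. Lower Tsc2 function acting on genes wherever they lie, as the whole cause, would give odds ratios near 1, and the lower bounds were 4.06 and 5.58. Read sequences were not used here. A variant in Atp6v0c or Rnps1 that moves reads to Atp6v0c-ps2 or Gm9825 was thus not separated from a changed level of the copies. An effect of Tsc2 stays open for Hecw2, Bnip3, Pcdh11x and 4930447C04Rik, which rose in both comparisons and had no such match. It also stays open for Galnt9 on chromosome 5, which fell in both, and for most of the 79 genes, of which 11.4% matched.

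The second pattern was that WT replicate 2 lay on the Hexb-null side of the largest axis of variation (10.1, against −17.8 to −12.1 in the other WT libraries and 12.8 to 16.4 in Hexb-/-). A mislabelled or mixed Hexb-null library was tested by its Hexb, which at 74.7 CPM lay above the other WT libraries, and Slc6a5 at 59.4 and Cst7 at 0.371 CPM lay far from Hexb-/- levels. Blood left in the tissue was tested by the red blood cell score, −0.355, below that of the other WT libraries. More microglia of the resting kind was tested by the excess of the antigen presentation score, which exceeded that of the homeostatic microglia score (0.144) by 1.39. These 3 tests argued against their explanations, and inflammation in that hemisphere, from infection or injury for example, may account for the values but was not tested. That library also held Tmem181b-ps (141 CPM) and Dynlt1b (4.58 CPM) near Tsc2+/- levels, and the cause of this was not tested.

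The third pattern was that genes near Hexb differed with the Hexb genotype more often than others. The odds ratios of 2.17 and 2.22 in comparisons sharing no libraries are consistent with a linked stretch of chromosome 13 that differs between Hexb-null and other mice. Genes in that stretch may also respond to Hexb loss itself, and Sv2c and Cmya5 could belong to either kind.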

How the results depend on the processing

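The lists with each library left out, the named genes without WT replicate 2 and the sums over copies were added after the data were seen, and the other alternatives were planned. Atp6v0c turned direction when reads of its copy were added (0.447 and 0.429 in the Tsc2 comparisons), though these sums cannot show whether its total RNA changed. H2-Ab1 and H2-Aa (Hexb-/- against WT, to 0.04 and 0.02) and the median of the interferon list (Tsc2+/- against WT, to 0.0152) turned direction without WT replicate 2. Of named gene values under the alternatives, 1056 kept their side of the threshold, 22 gained and 42 lost it, and of single list values 3673 kept it, 79 gained and 96 lost it.

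For the double mutant against Hexb-/-, the 52 genes became 115 with no filter beyond 1 read, 138 by DESeq2 and 377 by voom, which kept 51, 52 and 51 of the 52. For Tsc2+/- against WT, the 119 became 309 with no filter, 292 by DESeq2, 63 with only the 12 libraries compared and 20 with Xist as covariate, which kept 114, 119, 58 and 20. The interaction went from 0 by edgeR (749 unadjusted) to 3 with no filter and 1 each by DESeq2 and with Xist as covariate, and 0 by voom. With an estimated correlation the lists passing fell from 15 to 6 (Hexb-/- against WT), 2 to 0, 8 to 0 (Tsc2+/- against WT), 16 to 7, 17 to 6 (double mutant against WT) and 5 to 0 (interaction). The score of genes lower with Hexb loss passed with genes changed 2-fold (0.28, exact permutation p = 0.0152, 13 genes). Within 20 Mb of Hexb the odds ratio for the double mutant against WT was 1.33 (Fisher's exact p = 0.142), from 1.76. The cause was not tested in these cases.

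With 1 library left out, counts ranged from 1941 to 2640 (Hexb-/- against WT), 2869 to 3480 (double mutant against Tsc2+/-) and 2112 to 2669 (double mutant against WT). The double mutant against Hexb-/- ranged from 25 to 267: 267, 25, 32 and 29 without Hexb-/- replicates 1, 3, 4 and 5, and 133, 26, 28 and 31 without double mutant replicates 1, 2, 4 and 5. Tsc2+/- against WT ranged from 27 to 192: 27, 37 and 192 without WT replicates 2, 3 and 6, and 51, 60, 29 and 75 without Tsc2+/- replicates 2, 4, 5 and 6. The interaction ranged from 0 to 1, with 1 without WT replicate 6 and without Tsc2+/- replicate 4. Score differences ranged from −0.0462 to −0.0175 (exact permutation p 0.0238 to 0.413) and from 0.014 to 0.0289 (exact permutation p 0.013 to 0.186). Lists passing ranged from 15 to 16 (Hexb-/- against WT), 0 to 5 (double mutant against Hexb-/-), 2 to 12 (Tsc2+/- against WT, 2 without WT replicate 2), 15 to 18, 16 to 19 and 1 to 9 (interaction). For the double mutant against Hexb-/- they were 4 without WT replicate 2, 1, 5 and 4 without Hexb-/- replicates 2, 3 and 5, and 0, 5 and 4 without double mutant replicates 1, 2 and 6. For the interaction they were 1 and 8 without WT replicates 2 and 5, 9 without Tsc2+/- replicate 2, and 3 and 2 without double mutant replicates 1 and 3.

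Replicate numbers did not pair the libraries: same-numbered libraries correlated by −0.0526 to 0.156, over 0.1 in at most 1 of 6 pairs, and 1 to 3 of 6 correlated best with their own number. With replicate number as a block the counts were 2529, 58, 142, 3450, 2714 and 1 (interaction), and score differences were −0.0298 (p = 0.25, permutation within blocks) and 0.0165 (p = 0.188). In that fit 4 lists passed between the double mutant and Hexb-/-, with mitochondrially encoded genes higher (camera adjusted p = 0.0256) and immediate early genes lower (0.0309) added, and fatty acid synthesis was gained between the double mutant and Tsc2+/- (0.0408). Krt12 (edgeR adjusted p = 0.0602) and H2-T23 (0.0505) in Tsc2+/- against WT lost their calls.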

Other observations

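In this part the Tsc2+/- against WT response scores were chosen after the result was seen, as were the values without WT replicate 2, and the splits and the correlation relabelling were planned.

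The double mutant was also set against WT, which shows both losses together. By edgeR 2566 genes changed, 1167 higher and 1399 lower. Cst7 rose 33.8-fold (edgeR adjusted p = 2.32e-14), and Itgax (3.57, and 4.48 without WT replicate 2), Gpnmb (2.86) and Serpina3n (2.28) rose while Glra1 (−1.51), Slc6a5 (−1.28) and Sv2c (−0.77) fell. The genes of the Tsc2 comparisons stood beside them, with Tagap at 2.39, Hmga1b at 1.71, Atp6v0c at −0.75 and Rnps1 at −0.53 on the log2 scale by their own reads alone. Of the lists 17 passed, 6 of them with an estimated correlation: disease-associated microglia (24 of 26 rose; camera adjusted p = 1.68e-40, and adjusted p = 0.000757 with an estimated correlation), lysosome (35 rose and 1 fell of 47; 1.31e-27, and adjusted p = 0.000757 with an estimated correlation), interferon, complement, thalamus and general neurons. Endothelial and pericyte markers fell in 5 of 14 cases (camera adjusted p = 0.00277, and adjusted p = 0.261 with an estimated correlation) and fatty acid synthesis genes in 3 of 14 (camera adjusted p = 0.00299, and adjusted p = 0.173 with an estimated correlation).

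The Hexb response scores were compared between Tsc2+/- and WT, where Hexb was intact. The score of genes higher with Hexb loss was lower in Tsc2+/- by 0.073 (exact permutation p = 0.00217, the smallest of 924 arrangements), and that of genes lower with Hexb loss was higher by 0.0388 (exact permutation p = 0.00217). Without WT replicate 2 the differences were −0.0449 (exact permutation p = 0.00217) and 0.0356 (exact permutation p = 0.00433).

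Whether chance could give the numbers of changed genes was tested by regrouping the libraries, 100 splits per comparison with the real one included. For Hexb-/- against WT the real count was 2419 and the highest other 701, for the double mutant against Hexb-/- 52 and 25, and for Tsc2+/- against WT 119 and 3. For the double mutant against Tsc2+/- they were 3340 and 851, and against WT 2566 and 579. In each of these 5 comparisons 1 split of 100, the real one, gave as many genes. Chance was thus unlikely as the whole source but not excluded, since only 100 splits were run. Mixed splits also hold part of the real difference within each side, which widens the spread there and can lower their counts. For the double mutant against Hexb-/-, leaving out 1 library gave as few as 25 genes, the same as the highest other split. For the interaction the real count was 0 by edgeR (749 unadjusted; 1 by DESeq2 and 0 by voom) and the highest other 3. With a real count of 0 any split gives as many, here 100 of 100, so this test says nothing about chance.

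Chance axes of variation between libraries were tested as the source of the shared Tsc2 folds in both Hexb backgrounds. The correlation of 0.316 across genes was reached by 1 of 100 relabellings, the real one, with 0.108 as the highest other. Chance axes were thus unlikely as the whole source but not excluded, since only 100 relabellings were run. Such relabelling cannot separate lower Tsc2 function from a linked stretch of chromosome 17 or anything else that follows the Tsc2 groups.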
